A study of Arabidopsis thaliana with 64 samples.

How the data were processed

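The series holds 64 arrays with 2 channels, each comparing total RNA of an Arabidopsis line with total RNA of a comparator. The tissue and the dyes are not given in the sources used here. The labels name 14 single lines, each measured under 8 h and under 16 h of light, and 2 double mutants with FCA. The wild type was the comparator of 13 single lines, and C24 was the comparator of FLC20. The plants were 12 days old, except for FLC20 at 9 days. The labels form 32 groups of 2 arrays, 1 with the dyes swapped and 1 unswapped. Whether wild type RNA was shared between arrays is not given.

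Per the labels' descriptions, the authors put the arrays through a spatial normalization (Wilson and others), and the titles name the array files of a GenePix scanner. The deposited values are linear ratios of both channels, with a median of 1 on every array. The background correction, the spot filters, the direction of the ratio and the handling of swapped arrays are not given. Of 884736 deposited ratios 146 were missing, at most 32 on 1 array. Between 10.3% and 11.6% of the ratios of an array were exactly 1. No scanner files were used here, so signal over background is unknown.

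The deposited ratios were taken to log2 and kept otherwise as given. Whether swapped arrays had already been turned was settled from the values. After the mean of all arrays of the same orientation was subtracted, the 2 arrays of a group correlated positively over probes in 22 of 32 groups and negatively in 10, of which 2 lay below -0.3. The deposited ratios were therefore treated as running the same way on swapped and unswapped arrays. The 2 arrays of a group agreed weakly over probes, with a median r of 0.0286, and of 0.123 after that subtraction. Arrays of different groups with the same orientation had a median r of 0.157 before it.

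The array holds 13824 probes. The platform annotation gave 1 gene name to 6341 probes, several to 0 and none to 7483. Names were updated through the gene identifiers of the TAIR10.1 gene table, which matched 6322 of the named probes and missed 19, and no coordinates were used. The named probes cover 5164 genes. Probes of 1 gene were tested separately, and other probes of a named gene are given where they differ. AT1G54410 has 50 probes, whose log2 ratios had a median SD of 0.171 within an array.

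A single limma model (limma 3.58.1 in R 4.3.3) was fitted to all arrays, with a mean per group and a term for dye orientation, followed by empirical Bayes moderation with 5.17 prior degrees of freedom beside 30 residual degrees of freedom. The GI_16h arrays carry the same biological replicate number and were averaged to 1 replicate. Probes needed values on at least 48 arrays, which removed 0 probes. Contrasts were the mean of both day lengths for each single line, 16 h minus 8 h for each single line, each of the 4 double mutant groups, the autonomous class (FCA, FPA, FVE, FY) minus the photoperiod class (CO, FD, FE, FHA, FT, FWA, GI), and the mean of the 13 lines set against wild type. The p-values are two-sided and were adjusted by Benjamini-Hochberg within each contrast. A probe is said to be called, or to have risen or fallen, where the adjusted p lay under 0.05. Standard errors are limma's moderated ones. The dye term itself had an adjusted p under 0.05 for 3373 probes.

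The labels conflict for 3 groups. The titles of FCAVRN1_vs_FCA say 16 h and the descriptions short days. The titles of FCAVRN1_vs_WT say 8 h and the descriptions long days. The titles of the FVE 16 h arrays say 16 h and the descriptions short days. FVE was grouped by its titles. No contrast of the FCAVRN1 groups used a day length. The hours in their titles were used for the replicate block, for the comparison of residuals by replicate number and for the colours of a figure.

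The design, the gene lists, the classes, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 16 mutated loci. Per line and double mutant group it took the 3 named probes with the largest rise and the 3 with the largest fall, among called probes of the same sign on every array. For each day length difference it took as many, among called probes whose 16 h values all lay beyond all 8 h values in the direction of the difference. For the class contrast and for the mean of the 13 lines it took up to 12 in each direction, with the sign on at least 75% of the arrays. Up to 4 members of each list and at most 2 unnamed probes in each direction were added.

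There were 12 lists, which cover the mutated loci, flowering time regulators, circadian clock, gibberellin, photosynthesis, flavonoids and anthocyanin, cold and drought, salicylate defence, jasmonate defence, floral organ identity markers, seed storage markers and root markers. Lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, over probes averaged per gene. The Benjamini-Hochberg adjustment ran over 40 tests of list and contrast. Profile similarity was the mean Pearson r over probes between the 8 h profile of a line and the 16 h profile of another, within and between classes, with a two-sided exact permutation test over all 330 assignments of the 11 lines to the classes. Intervals of shares are exact Clopper-Pearson intervals at 95% and treat probes or genes as independent, which they are not.

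The model was tested on a simulated data set of 13824 probes, with independent normal noise per array. In FD 100 probes were changed by log2 0.5 and another 100 by log2 1, and likewise other probes in the autonomous lines. For FD against wild type the model recovered 83 of the smaller and 100 of the larger changes, with 12 false calls in all. For the class contrast it recovered 95 and 100, with 7 false calls in all. Residuals of real arrays of different groups correlated at up to 0.544, so false calls there need not be as few.

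The alternatives were no dye term, the replicate number as a block, arrays scaled to a common spread, quantile normalization, other filters on missing values, a robust prior, array weights, the arrays of a comparison alone, probes of a gene averaged, each line against the mean of the other lines, the GI_16h arrays as 2 replicates, FVE left out, and each array or line left out in turn. Chosen after seeing the data were ratios of exactly 1 set to missing, each day length alone for the class contrast and for the mean of the 13 lines, and the GI_8h arrays left out. Figures were drawn with matplotlib 3.10.9. Of the 16 mutated loci only FPA is named on the array, so that no other locus could be checked in its own line.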

Results

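The arrays compared RNA of Arabidopsis lines named for flowering loci with RNA of a comparator, and each single line was measured on 4 arrays, 2 under 8 h and 2 under 16 h of light. CO, FD, FE, FHA, FT, FWA and GI are loci of the photoperiod pathway, which promotes flowering in long days. FCA, FPA, FVE and FY belong to the autonomous pathway, which promotes flowering in both day lengths. GAI encodes a repressor of gibberellin responses, SOC1 integrates several flowering pathways, and FLC is a repressor of flowering. The alleles and the nature of the FLC20 line are not given in the sources used here. FCAVRN1 and FCAVRN2 were measured in 4 groups of 2 arrays, against wild type or against FCA. Each array gave between 13792 and 13824 ratios, and the share of ratios beyond 2-fold ran from 0.0868% to 5.14% with a median of 0.286%.

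The direction of the ratios is not settled by the labels. A positive log2 ratio is taken as higher in the line, which is likely because the descriptions compare each line to its comparator and the line is in channel 1 of the unswapped arrays. Only FPA of the mutated loci has a named probe, and its log2 ratio in the FPA line was -0.04 ± 0.07 (SE, n = 4), which decides nothing. Arrays of different groups reached an r over probes of 0.806 with the same orientation and of 0.647 with opposite ones. The 2 arrays of a group, which have opposite orientations, reached at most 0.584. The cause was not tested. Of 992 pairs of arrays of the same orientation and of different groups, 7 correlated below -0.3 over probes. The lowest were -0.461 between FPA_8h replicate 1 and GI_8h replicate 1, -0.457 between FLC20_8h replicate 1 and GI_8h replicate 1, and -0.424 between FCA_16h replicate 1 and FCAVRN1_vs_WT replicate 1. With the sign turned, every rise in the text is a fall and every fall a rise, and the counts of higher and lower probes exchange. Sizes, p-values and total counts stay as they are.

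The first question was which transcripts differ between each line and its comparator. Counts of called probes ran from 0 in CO to 842 in FLC20. Their order depends on the processing: with scaled arrays FLC20 had 228, FD 756, FE 88, CO 40 and GI 33, and in fits to the arrays of a line alone FD had 1410, CO 170, FLC20 24 and FY 0 by limma (1712 at an unadjusted p under 0.05). Unless another number is given, named probes of a line over both day lengths kept their sign on each of its 4 arrays. Each such value is a mean of 4 arrays with its standard error. Set against the mean of the other lines, which removes what all lines share, 28 of 84 named changes were still called and 56 were not.

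**Figure D1:**
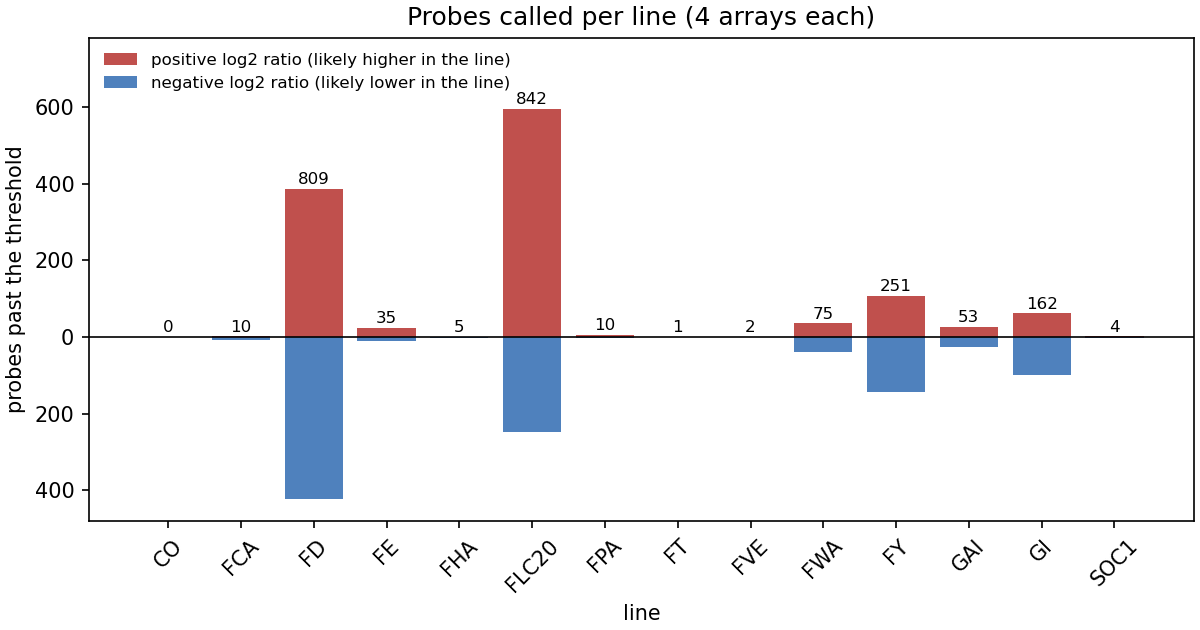
Called probes per line over both day lengths (y axis, number of probes, lower ones drawn downward), with the total printed above each line. FLC20 (842), FD (809), FY (251) and GI (162) have the highest totals in this fit, an order that changes with scaled arrays (FD 756, FLC20 228), CO has 0, and the direction higher in the line is likely, not settled.

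In FD, AT4G27450 fell on all 4 of its probes, by 1.42 ± 0.21 on the log2 scale on the strongest (adjusted p = 6.5e-05) and by 0.81 on the weakest. AT3G15450 changed by -1.25 ± 0.20 (adjusted p = 0.00014) and by -1.06 on its other probe. SWEET10, a sugar transporter, rose by 0.91 ± 0.18 (adjusted p = 0.0018), with means of 0.38 under 8 h and 1.44 under 16 h, a difference that was not called. AT1G80130 rose by 0.84 ± 0.12 on 1 probe and by 0.78 on the other, and AT4G33720 by 1.02 ± 0.30 (adjusted p = 0.036). In all 809 probes were called in FD, 386 higher and 423 lower. The count was 239 without FD_8h replicate 1, 386 without FD_16h replicate 1 and 261 without FD_16h replicate 2, and the call of AT4G33720 was lost without any of the 4 arrays (adjusted p up to 0.27, without FD_16h replicate 2). Against the mean of the other 12 lines the FD count was 89, and the calls of AT4G27450 (-0.83 ± 0.22 and -0.75 ± 0.20, adjusted p 0.069 and 0.068), SWEET10 (0.70 ± 0.19, 0.07) and AT4G33720 (1.24 ± 0.31, 0.051) were lost. AT4G33720 changed no less there, so its lost call does not show a smaller effect.

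In GI, AT4G27450 fell on all 4 of its probes too, with changes of -1.48 ± 0.26 (adjusted p = 0.0014), -1.26, -1.18 and -0.73. AT1G19530 fell by 1.4 ± 0.22 (adjusted p = 0.00023), while its other probe stood at 0.00. AT2G34810 rose by 1.1 ± 0.19 (adjusted p = 0.00096). AT4G09620 rose by 0.96 ± 0.15 and AT2G44300 by 0.83 ± 0.19, but their other probes stood at -0.05 and at 0.16 and 0.19. The GI count was 162 probes, 62 higher and 100 lower, and it was 966 without GI_8h replicate 2 (692 of them higher, so the balance turned), 419 without the unswapped GI_16h array and 59 without both GI_8h arrays, which correlated at -0.509. Array weights ended the call of AT4G27450 (adjusted p 0.092), the comparison with the mean of the other lines ended those of AT4G27450 (-0.90 ± 0.27 and -0.83 ± 0.24, adjusted p 0.26 and 0.22), AT1G19530 (-0.94 ± 0.22, 0.081) and AT2G44300 (0.71 ± 0.20, 0.19), and without GI_8h replicate 2 AT2G44300 was not called (0.13). Without both GI_8h arrays AT1G19530 was still called, but AT4G27450 (0.088 and 0.096), AT2G34810 (0.091), AT4G09620 (0.07) and AT2G44300 (0.1) were not.

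In FE, ALDH10A8, an aldehyde dehydrogenase, fell on its 3 probes, by 1.55 ± 0.14 (2.93-fold, adjusted p = 1.6e-09), 1.4 ± 0.11 (adjusted p = 2.3e-10) and 0.79 ± 0.12 (adjusted p = 0.00077). AMY1, an alpha-amylase, rose by 1.01 ± 0.21 (adjusted p = 0.019), with 0.48 on its other probe (adjusted p = 0.11). FDH, a formate dehydrogenase, and AT1G72910 each rose by 0.59, with standard errors of 0.12 and 0.14. AT2G43590 changed by -0.88 ± 0.19 (adjusted p = 0.025), and its other probes stood at -0.64, -0.70 and 0.01, not called. Of 35 called probes 24 were higher and 11 lower, and the count was 14 without FE_8h replicate 1, 8 without FE_8h replicate 2 and 20 without FE_16h replicate 1 (4 of them higher, so the balance turned). Against the mean of the other lines it was 7, 0 of them higher, and AMY1 (0.97 ± 0.22, adjusted p 0.13), FDH (0.35 ± 0.12, 0.78), AT1G72910 (0.31 ± 0.14, 1) and AT2G43590 (-0.77 ± 0.20, 0.22) were not called. Both ALDH10A8 probes named by the rule were called with any array left out, whereas FDH, AT1G72910 and AT2G43590 were called in no such fit (adjusted p up to 0.31, without FE_8h replicate 1) and AMY1 was lost without FE_8h replicate 1 (0.26), FE_8h replicate 2 (0.11) or FE_16h replicate 1 (0.25).

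In FWA, AT3G32240 rose by 1.93 ± 0.08 (3.80-fold, adjusted p = 1.8e-18), and the unnamed probe SP0000122314 by 2.11 ± 0.14 (4.31-fold, adjusted p = 7.3e-13). AT5G54970 rose by 0.74 ± 0.10 and AT2G34810 by 0.63 ± 0.15, while AT1G19530, AT2G32150 and AT2G05540 fell by 0.77, 0.69 and 0.67. The other probe of AT1G19530 stood at 0.14. In FWA 75 probes were called, 36 higher and 39 lower, and the count was 739 without FWA_16h replicate 1 (547 of them higher), 8 without FWA_16h replicate 2, 26 without FWA_8h replicate 1 and 43 without FWA_8h replicate 2. AT3G32240, AT5G54970 and SP0000122314 were called with any array left out, and the other 4 genes were lost without FWA_8h replicate 1 (adjusted p 0.12 to 0.21), FWA_8h replicate 2 (0.054 to 0.27) or FWA_16h replicate 2 (0.23 to 0.38), and AT2G05540 also without FWA_16h replicate 1 (0.062). Against the mean of the other lines the FWA count was 6, and AT1G19530 (-0.25 ± 0.18, adjusted p 0.78), AT2G05540 (-0.25 ± 0.16, 0.74), AT2G32150 (-0.54 ± 0.15, 0.28) and AT2G34810 (0.44 ± 0.16, 0.39) were not called.

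In SOC1, 4 probes were called. AT2G34655 rose on both of its probes, by 1.78 ± 0.12 (3.43-fold, adjusted p = 3e-13) and 1.63 ± 0.10 (adjusted p = 1e-13), and the unnamed probe SP0000126804 fell by 0.76 ± 0.08 (adjusted p = 1.8e-07). These 3 were called with any array left out. The remaining one, SP0000126145, fell by 0.44 and was called in no such fit (adjusted p up to 0.61, without SOC1_8h replicate 2).

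**Figure D2:**
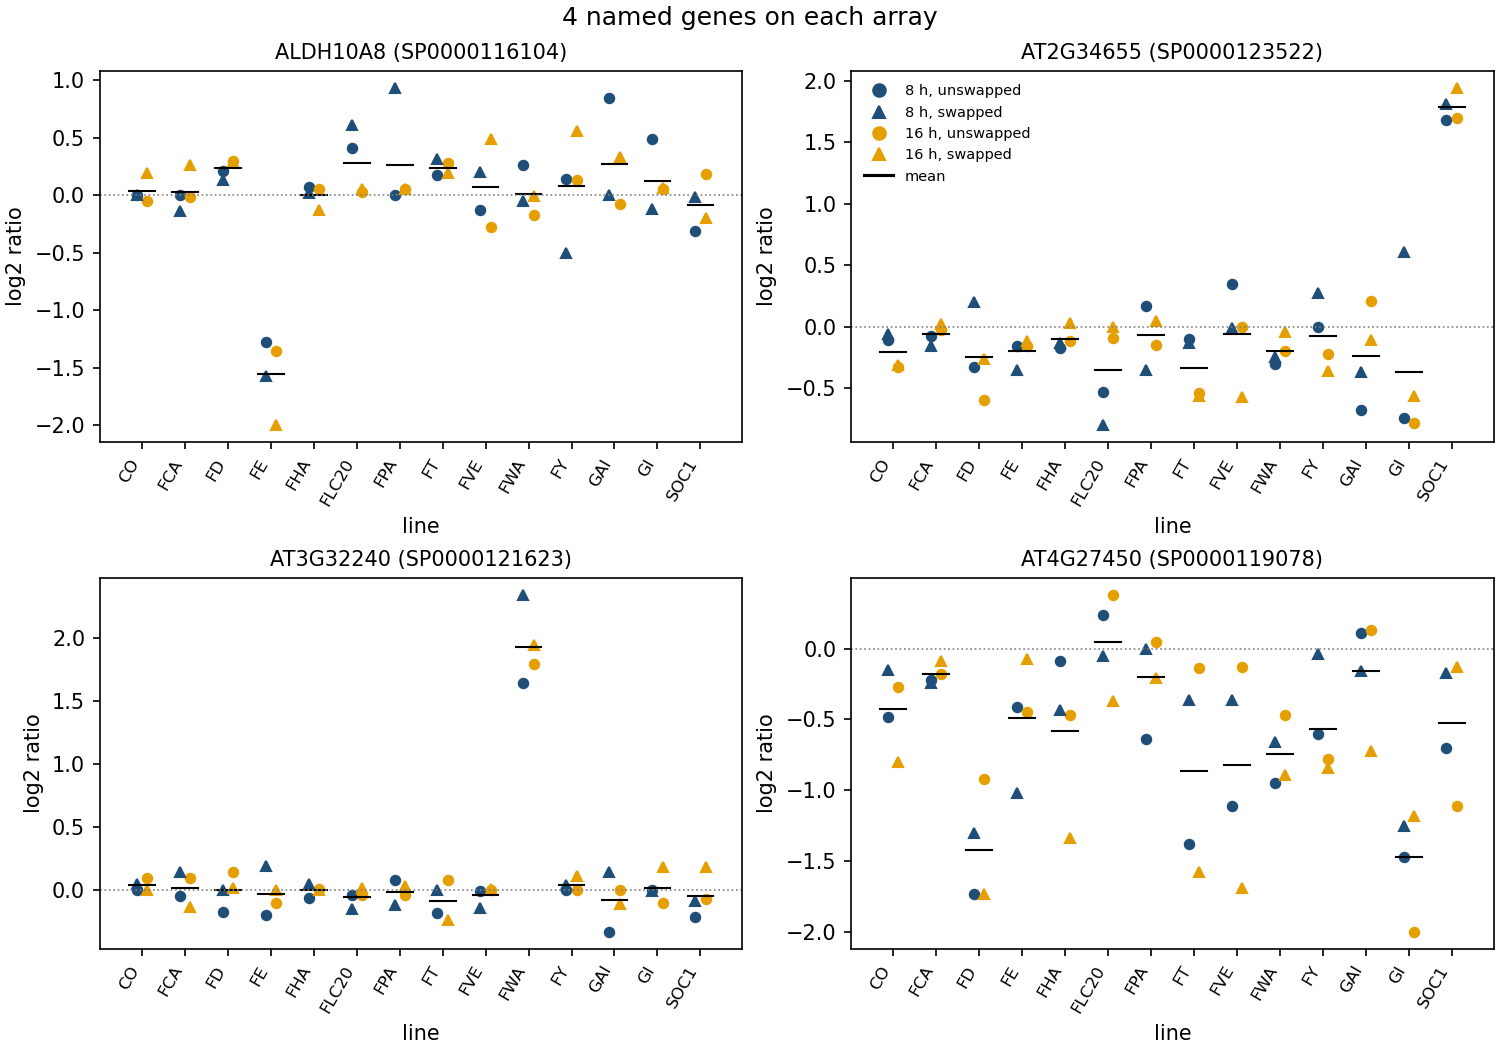
Log2 ratio (y axis) of ALDH10A8, AT2G34655, AT3G32240 and AT4G27450 on each array of the 14 lines (x axis), with the mean per line as a bar. ALDH10A8 is low on the FE arrays (-2 to -1.28), AT2G34655 is high on the SOC1 arrays (1.68 to 1.94), AT3G32240 is high on the FWA arrays (1.64 to 2.34), and AT4G27450 is below 0 on 48 of the 52 arrays of the lines other than FLC20.

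Among the autonomous lines, the unnamed probe SP0000127622 rose by 1.54 ± 0.15 in FCA (2.92-fold, adjusted p = 3.4e-08), 1.28 ± 0.15 in FVE (adjusted p = 3.8e-06) and 0.82 ± 0.15 in FY (adjusted p = 0.0023). In FPA it stood at 0.49 ± 0.15 (adjusted p = 0.16). In the other lines set against wild type it lay between -0.21 and 0.14, and in FLC20 against C24 it fell by 2.17 ± 0.15 (4.5-fold, adjusted p = 6.6e-13). Its calls in FCA, FVE and FLC20 held with any array left out.

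PDF1.2, a plant defensin induced by jasmonate and ethylene, fell in FCA by 1.52 ± 0.29 (adjusted p = 0.012), with means of -0.76 under 8 h and -2.28 under 16 h and -1.13 on its other probe (adjusted p = 0.086). The call was lost without FCA_8h replicate 1 (adjusted p 0.17) and FCA_16h replicate 1 (0.6). AT5G28740 fell by 0.28 ± 0.06 (adjusted p = 0.026), a call lost without any of the 4 arrays (adjusted p up to 0.25, without FCA_16h replicate 2). The FCA count of 10 (2 higher, 8 lower) was 51 without FCA_8h replicate 2 (43 of them higher, so the balance of directions turned) and 4 without FCA_16h replicate 1.

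In FY, AT4G30570 rose by 0.71 ± 0.09 (adjusted p = 0.00011), AT5G48540 by 0.71 ± 0.14 (adjusted p = 0.0036) and AT1G51650 by 0.65 ± 0.16 (adjusted p = 0.027). AT1G74940 fell by 1.00 ± 0.26 (adjusted p = 0.034), AT2G35410 by 0.68 ± 0.12 (adjusted p = 0.002) and PRK, the phosphoribulokinase of the Calvin cycle, by 0.68 ± 0.18 (adjusted p = 0.034), with -0.57 and -0.56 on its other probes, which were not called. PDF1.2 changed by 1.17 ± 0.29 (adjusted p = 0.024), with that sign on 3 of 4 arrays. Of 251 called probes 108 were higher and 143 lower, and the count was 2 without FY_16h replicate 1, 46 without FY_8h replicate 2 and 163 without FY_8h replicate 1. AT4G30570 alone of the 6 rule-named genes was called with any array left out, the other 5 were lost without FY_16h replicate 1 (adjusted p 0.098 to 0.36), AT1G74940 and PRK were called in none of the 4 fits, AT1G51650 in 1 and AT5G48540 in 2, and against the mean of the other lines the count was 5.

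In FPA all 10 called probes had an adjusted p of 0.044. OEP16-3 rose by 0.41 ± 0.08, TUA2, an alpha-tubulin, by 0.38 ± 0.08 and AT1G29670 by 0.33 ± 0.07, and AT4G25310 fell by 0.34 ± 0.07. The other probes of the last 3 stood at 0.05, -0.14 and -0.06. With no dye term, scaled arrays or array weights limma called 0 probes in FPA, so none of these genes. At an unadjusted p under 0.05 there were 1286, 1324 and 1239. Each of these 4 genes was called in 1 of the 4 fits with an array left out. The count was 638 without FPA_8h replicate 2 (489 of them higher) and 0 by limma without FPA_16h replicate 1 (836 at an unadjusted p under 0.05). In FVE SP0000115969 fell by 0.60 ± 0.11 (adjusted p = 0.026), and the count of 2 was 4 without FVE_8h replicate 2 and 173 without FVE_16h_by_title replicate 2 (48 of them higher). The call of SP0000115969 was lost without FVE_8h replicate 2 (adjusted p 0.074), FVE_8h replicate 1 (0.39) or FVE_16h_by_title replicate 1 (1).

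In FLC20 the unnamed probe SP0000127648 rose by 3.15 ± 0.15 (8.87-fold, adjusted p = 2.8e-17). AMY1 rose by 1.47 ± 0.21 (adjusted p = 2e-05), and by 0.50 on its other probe (adjusted p = 0.018). AT1G75280 rose by 1.31 ± 0.20 (adjusted p = 4.9e-05). DSK2, a ubiquitin receptor, rose by 1.44 ± 0.22 on 1 probe, while its others stood at -0.13 and -0.33. AT2G07770, AT5G02160 and AT5G48490 fell by 0.79, 0.76 and 0.67, and the other probe of AT5G02160 stood at -0.59 (adjusted p = 0.053). Scaling and quantile normalization ended the calls of AT2G07770 (0.079 and 0.12) and AT5G48490 (0.14 and 0.18). Of 842 called probes 595 were higher and 247 lower, and the count was 163 without FLC20_8h replicate 1, 1278 without FLC20_8h replicate 2 and 125 without FLC20_16h replicate 2. The rises named here held with any array left out, and the 3 falls were lost without FLC20_16h replicate 2 (adjusted p 0.31, 0.093 and 0.16). AT2G07770 was also lost without FLC20_8h replicate 2 (0.23), and AT5G48490 was called in none of the 4 fits.

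In GAI, AT1G75280 rose by 0.86 ± 0.20 (adjusted p = 0.039), AT3G09200 by 0.66 ± 0.15 (adjusted p = 0.041) and AT1G27030 by 0.53 ± 0.11 (adjusted p = 0.017). NDP1 and AT4G03740 each fell by 0.45 and AT5G45950 by 0.38, with -0.22 on its other probe (adjusted p = 0.33) and its call lost with probes averaged (-0.30, 0.073). The transcript of FPA stood at -0.34 ± 0.07 (adjusted p = 0.025), negative on 3 of 4 arrays. In GAI 53 probes were called, 27 higher and 26 lower, and the count was 10 without GAI_8h replicate 1, 1078 without GAI_8h replicate 2 (445 of them higher), 3 without GAI_16h replicate 1 and 15 without GAI_16h replicate 2. All 6 rule-named genes were lost without GAI_16h replicate 1 (adjusted p 0.078 to 0.23), NDP1 was called in 2 of the 4 fits with an array left out and the other 5 in 1 each, and against the mean of the other lines limma called 0 probes (1222 at an unadjusted p under 0.05).

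CO had 0 calls by limma, with 515 probes at an unadjusted p under 0.05, and the count was 3 without CO_8h replicate 1 and 2 without CO_8h replicate 2. FT had 1, SP0000115969 at -0.65 ± 0.11 (adjusted p = 0.014), and the count was 0 by limma without FT_16h replicate 1 (623 at an unadjusted p under 0.05) and 25 without FT_16h replicate 2 (6 of them higher). FHA had 5, none of them named: SP0000127834 fell by 0.96 ± 0.11 (adjusted p = 1.6e-06), SP0000127476 fell by 0.71 ± 0.11 and SP0000119123 rose by 0.90 ± 0.18. The FHA count was 2 without FHA_8h replicate 1 or without FHA_16h replicate 1, and 3 without FHA_16h replicate 2. Of these 3 probes SP0000127834 was called with any array left out, and the other 2 were lost without FHA_8h replicate 1 (adjusted p 0.38 and 1) or FHA_16h replicate 1 (0.18 and 0.21).

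The fixed lists were thinly covered by named probes. For photosynthesis 7 of 39 genes were measured, by 14 probes. In FD 4 of these probes fell and 1 rose (7 called when adjusted over the list alone), among them PSBW, of photosystem II, at -0.71 ± 0.18 (adjusted p = 0.013), LHCB1.5, a light-harvesting protein, at -0.50 ± 0.13 (adjusted p = 0.012) and LHCB4.1 at 0.48 ± 0.15 (adjusted p = 0.042). In FY 1 fell (6 over the list alone), LHCB4.2 at -0.63 ± 0.14 (adjusted p = 0.011), and in FWA 1 fell (3 over the list alone), LHCB1.5 at -0.61 ± 0.13 (adjusted p = 0.017). As a set, the 7 genes were lower in FY (median -0.28, 6 of 7 genes negative, camera adjusted p = 0.0093) and in SOC1 (median -0.19, 6 of 7 negative, camera adjusted p = 0.048). With an estimated correlation both calls were lost (adjusted p = 0.82 in each).

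Of the cold and drought list 3 of 23 genes were measured. COR47, a dehydrin, stood at -0.37 ± 0.08 in GI (adjusted p = 0.017, negative on 3 of 4 arrays), and KIN2, induced by cold, rose by 0.93 ± 0.26 in FCAVRN2_16h (adjusted p = 0.024, n = 2). In the mean of the 13 lines COR47 was lower on 2 probes, at -0.07 ± 0.02 (adjusted p = 0.0078, negative on 31 of 52 arrays) and -0.10 ± 0.03 (0.0059, 36 of 52), and ZAT10 was called neither there nor in any line. The jasmonate list held 2 of 19 genes, on 3 probes, with PDF1.2 as given and no call for the other over all probes. Adjusted over the list alone, all 3 probes were lower in FCA and FVE and higher in FPA, FWA and FY. By that adjustment 2 were lower in FD, 2 higher in GI and 1 lower in FLC20. The median of the 3 was -1.13 in FCA. In the double mutant groups set against wild type it was 0.59 (FCAVRN1_vs_WT) and 0.12 (FCAVRN2_8h), with 0 calls by either adjustment. Flowering time regulators had 2 of 30, of which LUMINIDEPENDENS (LD), of the autonomous pathway, changed by -0.37 ± 0.10 in FCAVRN2_16h (adjusted p = 0.019, n = 2). With scaled arrays, quantile normalization or array weights neither KIN2 nor LD was called there. Gibberellin had 2 of 26 (SLY1, a signalling component, rose by 0.12 ± 0.04 in the mean of the 13 lines, adjusted p = 0.019), and flavonoids and anthocyanin had 1 of 23 (DFR, an enzyme of anthocyanin synthesis, 0.12 ± 0.04, adjusted p = 0.032). Salicylate defence (WRKY53) had 1 of 13 and root markers (EXPA7) 1 of 11, with no call. The circadian clock (19 genes), floral organ identity (10) and seed storage (9) lists had 0 measured genes, so they could not be tested.

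The second question was whether a line differs from its comparator more under 1 day length. Over the 14 lines 21 probes were called for 16 h minus 8 h. In GAI there were 18, 3 higher and 15 lower under 16 h. PSAE-1, of photosystem I, differed by -1.21 ± 0.25 (adjusted p = 0.026), with a mean of 0.61 under 8 h and -0.61 under 16 h, and its other 3 probes stood at -0.66, -0.39 and -0.35, not called. MSRB5, a methionine sulfoxide reductase, differed by 1.17 ± 0.25 (adjusted p = 0.045, other probe 0.43, not called), AT2G34620 by -1.14 ± 0.24 and AT5G28040 by -1.03 ± 0.23. In GI 2 probes were called, AT2G26490 at -1.76 ± 0.21, which rests on 1 array (-0.07 without the unswapped GI_16h array, -3.44 without the swapped one), and SP0000123641 at -1.69 ± 0.30, and in FLC20 SP0000127630 at 1.62 ± 0.23. GI_16h counts as 1 replicate, so its spread is taken from the other groups. The other 11 lines had 0 calls by limma, with 279 (SOC1) to 1630 (FY) probes at an unadjusted p under 0.05.

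The 21 calls rest on few arrays. The total was 4 without GAI_16h replicate 1, 6 without GAI_16h replicate 2, 8 without GAI_8h replicate 1 and 997 without GAI_8h replicate 2. It was 676 without FWA_16h replicate 1, 335 without FLC20_8h replicate 2, 240 without FPA_8h replicate 2, 71 without FCA_8h replicate 2, 57 without FLC20_16h replicate 1 or without FY_8h replicate 2, 56 without FVE_16h_by_title replicate 2, 53 without FD_8h replicate 2, 47 without GI_8h replicate 2, 45 without FY_16h replicate 2 and 38 without FWA_8h replicate 2.

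The third question was whether the autonomous lines differ from the photoperiod lines. The class contrast called 43 probes, 22 higher in the autonomous class and 21 lower. Its standard errors and p-values measure the spread between arrays within a group, not the spread between the lines of a class. A large change in 1 line can therefore give a call. SP0000127622 differed by 1.07 ± 0.09 (adjusted p = 3.2e-09), and 34 of 44 arrays were positive in the autonomous or negative in the photoperiod class. AT2G05540 differed by 0.52 ± 0.10 (adjusted p = 0.0099) and AT2G32340 by 0.31 ± 0.07 (adjusted p = 0.031). AT2G34810 differed by -0.47 ± 0.10 (adjusted p = 0.017) and AT4G11190 by -0.38 ± 0.08 (adjusted p = 0.014), with -0.03 on its other probe. Profiles of 2 lines of the same class, one under 8 h and the other under 16 h, had a mean r of 0.154 over probes, and those of different classes 0.0624, a difference of 0.0915 (exact permutation p = 0.0242, 1 test, 330 assignments). The 42 photoperiod pairs had a mean r of 0.176. The 12 autonomous pairs had 0.0771, and 0.0382 without the highest of them (0.504, FY under 8 h with FPA under 16 h). Which lines carry the difference was not tested. A line's own 8 h and 16 h profiles had a mean r of 0.197, from 0.587 in GI and 0.487 in FD to 0.0642 in FY. Probes are not independent replicates.

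With 1 day length alone the class count was 7 under 8 h and 1 under 16 h, and of the probes named here SP0000127622 alone was called in each. It was 70 with scaled arrays and 69 with quantile normalization. The call of AT2G05540 was lost with no dye term (adjusted p 0.09), and that of AT4G11190 with probes averaged (-0.20, 0.053). The class count was 4 without FCA, 23 without FD, 97 without FVE, 18 without FWA and 21 without GI. It was 18 without FCA_16h replicate 1, 67 without FPA_8h replicate 2, 20 without FVE_8h replicate 2, 118 without FVE_16h_by_title replicate 1, 26 without FVE_16h_by_title replicate 2 and 24 without FY_8h replicate 1. SP0000127622 was called with any line left out, but without FCA the calls of AT2G05540 (adjusted p 0.68), AT2G34810 (0.63), AT4G11190 (0.051) and AT2G32340 (0.089) were lost. AT2G32340 was called with 3 of the 11 lines left out in turn, AT2G05540 was lost without FD (0.086), AT2G34810 without FWA (0.072) or GI (0.2), and AT4G11190 without FWA (0.098) or FY (0.12).

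The fourth question was what the 13 lines set against wild type share. In their mean, 3519 probes were called, 1884 higher and 1635 lower, with a median size of 0.11 on the log2 scale, and 5 of them lay beyond 1.5-fold. AT4G27450 fell on its 4 probes by 0.65 ± 0.06, 0.57, 0.50 and 0.39 (the first negative on 48 of 52 arrays, adjusted p = 1.9e-09). AT1G19530 (-0.53 ± 0.05, other probe 0.04), AT5G10040 (-0.44 ± 0.06), AT2G05540 (-0.43 ± 0.04), AT4G39675, AT5G17820 and AT5G25840 (each -0.34) fell too. PORB, of chlorophyll synthesis, fell on 3 probes by 0.39, 0.34 and 0.32, and its other 2 stood at -0.02. Of the photosynthesis list 9 probes fell and 1 rose (11 called over the list alone), but the camera test of the set had an adjusted p of 0.061.

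Among the rises in the mean of the 13 lines, AT1G80130 was highest of the named genes at 0.35 ± 0.03 (adjusted p = 4.4e-09, positive on 47 of 52 arrays). AT1G75280 (0.34), AT3G15460 (0.31), AT5G53730 (0.31), AT4G32470 (0.31), AT1G72910 (0.30), AT1G07750 (0.30), AT5G19440 (0.30) and AT4G20150 (0.29) rose, as did GSTU25, a glutathione transferase, and GR1, a glutathione reductase (each 0.33), and TPI, a triosephosphate isomerase (0.32). All named genes of this contrast were called with any of the 13 lines left out, and with each array or line left out the count ran from 2954 (without FD) to 3817 (without GI_8h replicate 1). The 8 h groups alone gave 562 calls and the 16 h groups alone 3736, and with the 8 h groups alone AT1G72910, AT1G07750, AT4G39675, AT5G17820, GSTU25 and TPI were not called (adjusted p 0.053 to 0.42). The p-values treat the arrays as independent, which shared wild type RNA would break. They also rest on the spread between arrays within groups, not on the spread between lines.

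The last question was what the double mutants change against wild type or against FCA. FCAVRN1_vs_FCA had 0 calls by limma, with 333 probes at an unadjusted p under 0.05. FCAVRN1_vs_WT had 2, AT5G04070 at -0.82 ± 0.13 (adjusted p = 0.0078) and SP0000120930 at -1.72 ± 0.30 (adjusted p = 0.014). Both rest on replicate 2: without it they stood at -0.32 and -0.15, and without replicate 1 at -1.32 and -3.29. FCAVRN2_8h, against wild type, had 1, SP0000126145 at -0.77 ± 0.12 (adjusted p = 0.0019). FCAVRN2_16h, against FCA, had 1085, 450 higher and 635 lower. In it AT4G07425 rose by 1.75 ± 0.53, AT5G34970 by 1.37 ± 0.43 and AT2G04970 by 1.15 ± 0.35 (adjusted p = 0.037, 0.041 and 0.037), and AT4G32330 fell by 1.34 ± 0.40, AT3G28550 by 1.19 ± 0.31 and DSK2 by 1.08 ± 0.32 (adjusted p = 0.034, 0.017 and 0.03), each on both arrays. Without replicate 2 the 3 rises stood at 0.75, 0.33 and 0.06 (adjusted p 0.84, 1 and 1), and without replicate 1 at 2.75, 2.42 and 2.24. AT4G32330 was called in neither fit (-1.63 and -1.05, adjusted p 0.15 and 0.26), nor was AT3G28550 (-1.58 and -0.80, 0.053 and 0.26), and DSK2 was lost without replicate 1 (-0.48, 0.58). DSK2 stood at 0.01 and 0.02 on its other probes, and AT3G28550 at -1.02 (adjusted p = 0.069), -0.49 (0.044) and 0.13 (0.62). The transcript of FPA changed by -0.49 ± 0.10 (adjusted p = 0.0059).

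The probe SP0000127622, higher in FCA than in wild type, stood at -0.08 ± 0.21 in FCAVRN1_vs_FCA, 0.13 ± 0.21 in FCAVRN1_vs_WT and 0.75 ± 0.21 in FCAVRN2_8h, none of them called, and at 1.31 ± 0.21 in FCAVRN2_16h (adjusted p = 0.00084). Without an array, FCAVRN1_vs_FCA had 18 (replicate 1 left out) or 2 (replicate 2) calls, FCAVRN1_vs_WT 204 or 1, FCAVRN2_8h 10 or 5 and FCAVRN2_16h 1600 or 237. Array weights, scaling and quantile normalization each left FCAVRN2_16h with 0 calls by limma (1676, 1575 and 1503 at an unadjusted p under 0.05), so that none of its named changes was called there. The call of SP0000127622 was also lost without FCAVRN2_16h replicate 2 (adjusted p 0.083), those of AT5G04070 and SP0000120930 without FCAVRN1_vs_WT replicate 2 (1 for each) and that of SP0000126145 without FCAVRN2_8h replicate 1 (0.12).

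**Figure D3:**
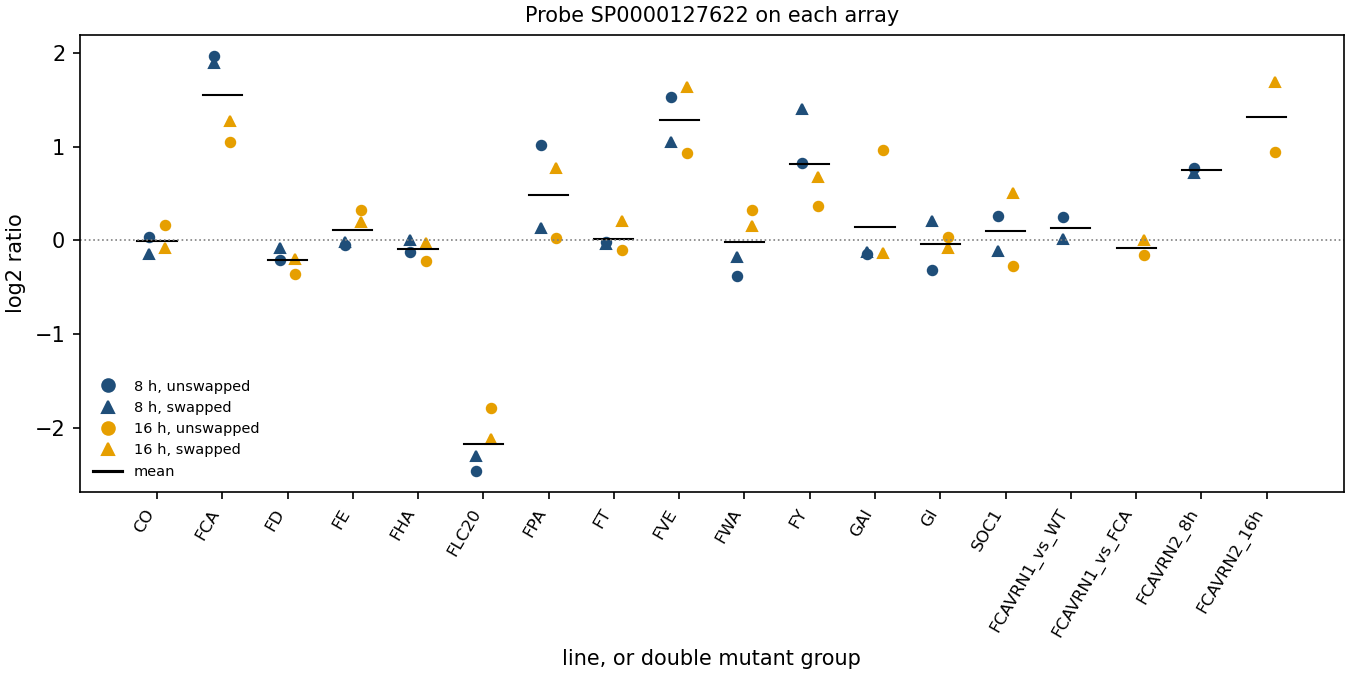
Log2 ratio of SP0000127622 (y axis) on each array of the 14 lines and of the 4 double mutant groups (x axis), coloured by the hours in the titles, with the mean as a bar. The FLC20 arrays lie between -2.46 and -1.79, the FCA arrays between 1.05 and 1.97, the FVE arrays between 0.93 and 1.63 and both FCAVRN2_16h arrays at 0.94 and 1.69.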

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

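The tests of the FLC20 signs, of random error in the double mutants and of linkage among the 2-fold changes were chosen only after the result was seen, and the double mutant and single line patterns were picked after the calls were known.

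The difference between day lengths was tested itself, and it was called for 18 probes in GAI, 2 in GI and 1 in FLC20. GI_16h counts as 1 replicate, which is assumed to vary like the other groups. In GAI the called differences of 16 h minus 8 h (log2) included MSRB5 at 1.17, SP0000120953 at 1.2, SP0000122775 at 0.8, PSAE-1 at -1.21, AT2G34620 at -1.14, AT5G28040 at -1.03, SP0000116015 at -1.54 and SP0000125291 at -1.5. Without GAI_16h replicate 1 none of these 8 was called (adjusted p 0.077 to 0.32) and without GAI_8h replicate 1 SP0000120953 and SP0000122775 alone were. Quantile normalization ended all 8 calls (adjusted p 0.056 to 0.12), and array weights all but that of SP0000120953 (0.053 to 0.14). The total over all lines fell from 21 to 4 without GAI_16h replicate 1, to 6 without GAI_16h replicate 2 and to 8 without GAI_8h replicate 1, and was 997 without GAI_8h replicate 2. In GI AT2G26490 stood at -1.76, but at -0.07 without the unswapped GI_16h array (adjusted p 1), and SP0000123641 at -1.69, a call lost without GI_8h replicate 1 (0.37) or the swapped GI_16h array (0.077). In FLC20 SP0000127630 stood at 1.62, lost without FLC20_16h replicate 2 (0.053).

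The autonomous and the photoperiod class differed in 43 probes by a test of that difference, whose p-values do not measure the spread between lines. Of 100 assignments of the 11 lines to groups of 4 and 7, 2 gave as many calls, the real one included. That share is under the 0.05 set beforehand. It comes from a sample of the 330 assignments, and the count itself ran from 4 to 97 with a line left out. Chance is therefore made less likely but is not excluded. The highest of the other assignments called 43 too, with FD, FHA, FT and GI as the group of 4. These are all photoperiod lines, and the 4 autonomous lines lie together in the other group, so this split follows the classes in part. With FCA left out 4 probes were called, and with FVE_16h_by_title replicate 1 left out 118. The count was 18 without FWA, 21 without GI, 23 without FD and 97 without FVE. The count fell to 0 without no line, but SP0000127622, called with any line left out, was enough to keep it above 0. For the other called probes this test cannot rule out 1 line as the cause. The count depends most on FCA among the lines, and without FCA the 4 named genes of this contrast were not called.

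The first pattern is the 3519 probes called in the mean of the 13 lines. The 8 h mean and the 16 h mean correlated at 0.429 over all probes. Wild type RNA shared only within a day length would not give that by itself. Effects of single lines under both day lengths would, however (own 8 h and 16 h profiles correlated at 0.587 in GI and 0.487 in FD). The r therefore cannot tell what part of the called probes came from shared RNA. With the 16 h groups alone many more probes were called than with the 8 h groups alone. Of the called probes 71.4% had the same sign in FLC20 (interval 69.8% to 72.8%), which was set against C24, so a feature of the wild type alone does not account for all of them. Of 100 random sign flips of whole lines 1 reached the real count, which is the real one, and the highest other called 1671. This points to a structure shared by many lines, which wild type RNA shared between arrays would give too. Open stay the mutated loci themselves, which the design names and which were not tested apart from the lines. Also open are shared wild type RNA as part of the cause, and effects of growth that set all lines apart from any wild type. The FLC20 arrays share the platform and the processing, so anything common to all arrays stays open as well.

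The second pattern is that the double mutant groups do not add up. For SP0000127622, FCAVRN1_vs_WT minus the sum of FCA and FCAVRN1_vs_FCA was -1.33 ± 0.33, which is 4.04 standard errors from 0, beyond random error as the limma model estimates it (-1.72 with FCA under 8 h, -0.95 under 16 h), and FCAVRN2_8h minus the sum of FCA and FCAVRN2_16h was -2.11 ± 0.33 (6.39 standard errors). If the comparators of FCAVRN1_vs_WT and FCAVRN2_16h had been exchanged in the labels, the other 9 probes called in FCA might move more in FCAVRN2_16h. The mean difference was -0.01 ± 0.05. Their means, turned to the sign in FCA, were 0.73 in FCA, -0.05 in FCAVRN1_vs_WT, -0.06 in FCAVRN2_16h and -0.01 in FCAVRN1_vs_FCA. In FCAVRN2_8h, set against wild type and outside the supposed exchange, the mean was -0.08. The change in FCA was thus absent there too, so these probes could not reveal an exchange. An effect of the VRN1 or VRN2 mutation that is alike in both groups of a double mutant cancels in its sum, so the sums speak against it as the cause. An exchange of comparators and an effect that depends on day length cannot be told apart here. The 9 probes on average lack the FCA change even in FCAVRN2_8h. The 2 groups of each double mutant also differ in day length, for FCAVRN1 by titles and by descriptions alike.

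The third pattern is the strongest changes of single lines, such as ALDH10A8 in FE, AT2G34655 in SOC1 (also called in FLC20, at -0.33) or AT3G32240 in FWA, of which the first 2 lie on the chromosome of the mutated locus. Sequence or expression differences that were carried along with the mutated locus might give such changes, and of 20 named changes beyond 2-fold 30% did lie there (interval 11.9% to 54.3%), against 19.6% expected, though 5 of the 20 alone were genes called in 1 line only (2 of the 5 lay there). Of 560 named genes called in 1 line only, most of them from FLC20 (247) and FD (207), 22% did (interval 18.6% to 25.6%), against 23.1% expected. A first version of the latter test would have counted any share not above the expected one against linkage, but it was replaced before the test was run by the stricter need for an interval wholly below it, which is not met. Linkage and other causes cannot be told apart by these shares, because both intervals hold the expected share. A whole chromosome was counted as linked, so a short segment around a locus could go unseen. AT3G32240 lies on another chromosome than FWA. No biological explanation was tested.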

How the results depend on the processing

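Chosen only after the result was seen were the tests with ratios of exactly 1 set to missing, with 1 day length alone and without the GI_8h arrays. No named change reversed its sign in any fit. The count for the mean of the 13 lines moved by more than 1.5 times with the 8 h groups alone and with no other setting, and those of single lines moved with several settings. The cause was not tested, except that fits with arrays left out hold fewer samples. Filters on missing values and a robust prior moved no count by more than 1.5 times. The difference in profile similarity was 0.0915, 0.077 with Spearman's r (p = 0.0333) and 0.131 over the 1000 most variable probes (p = 0.0212). Of the named changes 122 of 155 were still called with no dye term, 117 of 155 with scaling, 121 of 154 with quantile normalization, 111 of 154 with array weights, 137 of 154 with probes averaged, 144 of 153 with ratios of exactly 1 missing, and 69 of 120 in fits to the arrays of the comparison alone. Signal over background is not given, so what it limits is unknown.

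Counts that moved by more than 1.5 times follow, and each 0 is by limma with the number at an unadjusted p under 0.05 in brackets. With no dye term they were FPA 0 (1286), FWA 24, GAI 27, FCAVRN1_vs_WT 0 (712), FCAVRN2_16h 678 and 11 for the day length differences; CO (415) and FCAVRN1_vs_FCA (266) stayed at 0. Arrays with the same replicate number and hours had residuals with a median r of 0.0288 (-0.653 to 0.544, 33.8% of 450 pairs over 0.1). With different hours the median r was -0.0324 (22.9% of 480 pairs over 0.1). In most groups replicate 1 was the swapped array, so the dye term takes up most of any shared replicate effect. Whether the numbers pair samples can therefore not be told from these residuals. As a block the replicate numbers gave CO 6, FWA 123 and GAI 83, FCAVRN1_vs_FCA stayed at 0 (352), and 152 of 154 named changes were still called. Scaled arrays gave CO 40, FCA 53, FE 88, FHA 13, FLC20 228, FPA 0 (1324), FT 7, GAI 14, GI 33, SOC1 8, FCAVRN1_vs_FCA 6, FCAVRN2_8h 2, FCAVRN2_16h 0 (1575), class 70 and day length 8. Quantile normalization gave CO 43, FCA 51, FE 94, FHA 32, FLC20 133, FT 14, FY 160, GAI 26, GI 32, SOC1 14, FCAVRN1_vs_FCA 3, FCAVRN1_vs_WT 9, FCAVRN2_8h 4, FCAVRN2_16h 0 (1503), class 69 and day length 10. Array weights gave CO 56, FCA 59, FD 1390, FE 85, FHA 19, FLC20 550, FPA 0 (1239), FT 13, FWA 37, FY 561, GAI 6, GI 13, FCAVRN2_16h 0 (1676) and day length 114, with FCAVRN1_vs_FCA at 0 (568).

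With probes of a gene averaged CO had 4 and FPA 3, and FCAVRN1_vs_FCA 0 (287). With ratios of exactly 1 missing FPA had 24, FT 2, FVE 5, FWA 118, FCAVRN1_vs_FCA 2, FCAVRN1_vs_WT 5 and day length 79, and CO 0 (489). Against the mean of the other lines FCA had 45, FD 89, FE 7, FHA 1, FPA 0 (868), FT 0 (597), FVE 1, FWA 6, FY 5, GAI 0 (1222), GI 16 and CO 0 (170). Fitted to its own arrays CO had 170, FCA 42, FD 1410, FE 20, FHA 15, FLC20 24, FPA 0 (1130), FT 0 (1380), FVE 4, FWA 0 (1087), FY 0 (1712), GAI 0 (734) and SOC1 2, and GI and the double mutants have no residual degrees of freedom there. GI had 666 with GI_16h as 2 replicates and 59 without GI_8h. The class count was 97 without FVE, 7 under 8 h and 1 under 16 h, and the mean of the 13 lines had 562 under 8 h. The 2 called list tests became 0 with an estimated correlation.

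Scaling and quantile normalization also moved the split of directions. Of the called probes the higher ones were 1 of 5 in FHA, against 6 of 13 scaled and 16 of 32 quantile normalized, 0 of 1 in FT against 4 of 7 and 10 of 14, and 62 of 162 in GI against 17 of 33 and 17 of 32. In GAI 27 of 53 became 17 of 26 and in FPA 6 of 10 became 6 of 15 by quantile normalization, and in SOC1 2 of 4 became 3 of 8 by scaling. FCAVRN1_vs_WT had 0 of 2, then 1 of 3 and 1 of 9, and FCAVRN2_8h 0 of 1, then 1 of 2 and 1 of 4.

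With each array left out in turn, where a lone array is assumed to vary like the other groups, the counts ran from 0 to 3 in CO, 4 to 51 in FCA, 239 to 588 in FD, 8 to 26 in FE, 2 to 4 in FHA, 125 to 1278 in FLC20, 0 to 638 in FPA, 0 to 25 in FT, 2 to 173 in FVE, 8 to 739 in FWA, 2 to 246 in FY, 3 to 1078 in GAI, 113 to 966 in GI and 3 to 6 in SOC1. They ran from 2 to 18 in FCAVRN1_vs_FCA, 1 to 204 in FCAVRN1_vs_WT, 5 to 10 in FCAVRN2_8h and 237 to 1600 in FCAVRN2_16h. With lines left out too they ran from 4 to 118 for the class, 2954 to 3817 for the mean of the 13 lines and 4 to 997 for day length. The lows of 0 by limma came without CO_16h replicate 1 (636) or replicate 2 (327), FPA_16h replicate 1 (836) and FT_16h replicate 1 (623). The report names the arrays behind each move. Named changes were refitted with each array of their line or group left out. Those of the class and of the mean of the 13 lines were refitted with lines left out only, never with single arrays. Of 154 named changes 66 were called in every such fit and 16 in none.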

Other observations

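The hypotheses in this part came from the results and were tested on the same data, and the test on ratios of exactly 1 was chosen only after the result was seen.

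Several unnamed probes moved in many lines. In the mean of the 13 lines SP0000119123 rose by 0.80 ± 0.05 (adjusted p = 9e-14, positive on 46 of 52 arrays) and SP0000123199 by 0.69 ± 0.05 (44 of 52), and SP0000128902 fell by 0.60 ± 0.05 (45 of 52) and SP0000115969 by 0.52 ± 0.03 (48 of 52). SP0000119123 also rose in FLC20 against C24, by 1.61 ± 0.18, and in FD, by 1.5 ± 0.18. In GI SP0000123308 rose by 1.91 ± 0.24 and SP0000123171 by 1.78 ± 0.20, and the latter was also lower in the autonomous than in the photoperiod class, by -0.53 ± 0.10, a call lost without FCA (adjusted p 0.68) or GI (0.4).

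In the mean of the 13 lines several of the named genes that fell are known from responses to sugar starvation (AT4G27450, AT2G05540) or to low oxygen (AT1G19530, AT5G10040, AT4G39675). A hypothesis from this is that both responses are lower in the lines than in wild type. Of 2 lists written from memory after the calls were known, with the 12 genes that gave the idea left out, 17 other genes were measured, 11 of them negative with a median of -0.03. The camera p was 0.036 with the preset correlation and 0.1 with an estimated one, so that the hypothesis stays open. In single lines the camera direction of the combined list was down in each of the 14, but mostly without a low p. The unadjusted camera p ran from 0.01 in FT (0.05 with an estimated correlation) to 0.96 in FCA. Medians ran from -0.11 in GI to 0 in FE and FY. In CO, FE, FWA and FY 9 of the 17 genes of the combined list were negative. Its parts went both ways. The starvation list had a median of -0.22 in FD and -0.11 in GI, but 0.10 in FCA, where 2 of its genes were negative. The low oxygen list had a median of -0.10 in FCA, but 0.03 in FWA and in SOC1. Each list alone had a p of 0.11 (starvation, 9 genes) and 0.14 (low oxygen, 8 genes). Of the starvation list STR18 stood at -0.18, AT1G23390 at -0.13, and AKINBETA1 and AT3G15630 at -0.12, each called. AT4G10270, of the low oxygen list, stood at -0.24 ± 0.04 (adjusted p = 5.7e-05), while PDC2, a pyruvate decarboxylase of fermentation, stood at 0.05 ± 0.02 (0.095). Sugar levels and oxygen were not measured here.

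About 1 in 9 ratios were exactly 1, with a median of 11% per array (10.3% to 11.6%). A hypothesis is that each spot was divided by the median of a block of 9 neighbouring spots, which sets 1 spot of each block to 1, but the idea came from this share, so the share cannot test it, and no other test was run. With these ratios set to missing, the mean of the 13 lines had 2681 calls in place of 3519.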
